A study of Mus musculus with 12 samples.

How the data were processed

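RNA was sequenced from CD11b+ cells sorted as macrophages from bone marrow and from bone-associated cells of young and aged mice, 12 libraries in 4 groups of 3. Per the labels' protocols, sorted cells were lysed at once, RNA was extracted with a micro column kit, cDNA was made with a low-input SMART-Seq kit and libraries with a Nextera XT kit. Per the submitters' processing notes, the tools were Trimmomatic 0.32, STAR 2.4.2a and HTSeq 0.6.1 with the genome build GRCm38.p4. The deposited table holds raw read counts per gene symbol, not normalised by the authors, for 45664 genes, of which 17563 had no count in any library. How the bone-associated fraction was released from bone, which annotation was used and whether counting used strand are not given in the sources used here. Because the strand setting is not stated, reads of a gene and its antisense partner, such as Xist and Tsix, cannot be told apart. Counts of near-identical families (class I MHC, Cd209, Ear, haemoglobin and immunoglobulin genes) can be split between members and are uncertain for single genes.

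Groups were taken from the labels. The 3 mice of each age are described as individual animals, and the sample titles carry 1 code per mouse at both sites, so bone marrow and bone-associated libraries with the same code were taken as the same animal. The title of aged bone marrow replicate 2 carries a further suffix, R, whose meaning is not given in the sources used here. Without that library the interaction had 170 calls in place of 45. The pairing by code was checked by correlating, across genes with at least 5 CPM, each library's deviation from its group mean. Pearson's r for libraries with the same code was 0.287, 0.310 and 0.249 in aged mice and 0.0950, 0.0693 and 0.0769 in young mice, and every other pair within an age was at -0.0197 or lower. Genes are not independent replicates, so these values are descriptions. The numbers do not pair young with aged mice. No replicate pair differed by as little as sampling noise: chi-square per degree of freedom ranged from 34.5 to 182.

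Genes were kept with edgeR's filterByExpr (16209 genes) and scaled with TMM factors. Tests used edgeR 4.0.16 in R 4.3.3, quasi-likelihood F-tests with robust dispersion from 1 fit of all 12 libraries with a mean per group, and Benjamini-Hochberg adjusted p below 0.05 as the threshold for a call. The contrasts were aged against young at each site, bone-associated against bone marrow at each age, and the difference between the age effects at the 2 sites (the interaction). Log2 fold changes are printed with a standard error (SE) from the F statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD of 3 libraries. Where all 3 libraries of a group had no count, the fold is a lower bound against 3 counts over the group. Such floors, and the 95% intervals of ratios with 1 to 3 counts, cover counting error only, since reads without molecular identifiers are not independent molecules. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1, so single genes rest on the model across genes.

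A set of 36 gene lists, 20 of cell programmes and 16 of cell type markers, holding 687 symbols of which 3 were missing from the table, was tested with limma 3.58.1. The main test was camera with a preset correlation of 0.01, beside camera with an estimated correlation, and fry. List p values were adjusted over the 36 lists of a comparison. Called members are counted over all genes tested and also adjusted over the list alone. Coordinates are from the GENCODE M21 annotation of GRCm38, 1-based. Of the genes tested, 868 had no match there.

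The groups, tests, contrasts, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule takes, per comparison, the 6 highest and 6 lowest fold changes among called genes with at least 10 CPM in the higher group and no overlap between the groups' libraries, leaving predicted gene models and immunoglobulin or T cell receptor segments unnamed. The overlap condition was not used for the interaction. It adds up to 4 called members with the smallest adjusted p from the lists with most calls until about 30 genes are named, and 18 key genes of macrophage identity and interleukin-1 signalling. Where fewer than 3 genes pass in a direction, the 3 with the smallest unadjusted p are taken. Other members named as examples of a list were chosen after their values were seen, as called members with the smallest adjusted p. Some genes that these choices take are not reported here.

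The fit and list test were run on simulated data with 200 genes changed. Of genes simulated with a 2-fold and a 4-fold change, 26% and 62% were recovered for age in bone marrow (15531 genes), 28% and 68% for age in bone-associated cells (15536 genes) and 37% and 70% for site in young mice (15526 genes). Shares were 22% and 76% for site in aged mice (15510 genes) and 7.07% and 51% for the interaction (15513 genes). False calls numbered 4 to 6. A list shifted by 0.7 in log2 was called in all 5 comparisons and 0 of 35 others were. Gene correlation was not tested.

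Alternatives were DESeq2 size factors, library size alone, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, no low-count filter, a filter of 5 CPM in 3 libraries, fits of only the compared groups, a replicate block (the mouse code for site and interaction, the replicate number for age), other set tests, and leaving out each library in turn. Fits without genes on X and Y, and without immunoglobulin genes and markers of other cell types, were added after seeing the data. Scaling by library size alone moved the median log2 fold change of all genes by -0.13 in both age comparisons, by -0.40 in both site comparisons and by 0.00 in the interaction. Pseudocounts were not varied because the table holds counts.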

Results

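Cells sorted as macrophages were profiled by RNA sequencing from 2 sites, bone marrow and the bone-associated fraction, in C57BL/6 mice aged 3 months (young) or 24 months (aged). The sort took CD11b+ cells that were positive for F4/80 and negative for Ly6C. Each of the 4 groups held 3 libraries from separate mice, and the 2 sites of an age shared the same mice. The series title links ageing of blood stem cells to differences among macrophages of marrow regions, so the comparisons ask what age changes at each site and what differs between sites. Library totals ranged from 19564981 to 38317512 counts. Genes with a count averaged 20203 and 20195 in young and aged bone marrow and 17509 and 16150 in bone-associated cells. Whether this lies behind genes absent there was not tested. In a principal component analysis, component 1 held 37.1% of the variance and parted the sites, and component 2 held 18.2% and parted the ages. The 3 aged bone-associated libraries lay far apart on component 3 (9.60%; -48.1, 120.8 and -51.3) and component 4 (8.45%; -98.6, -6.99 and 94.4), more than those of any other group. Neutrophil transcripts were abundant despite the gate. The 19 neutrophil markers summed to 54550 ± 951.6 CPM in young and 53950 ± 9216 in aged bone marrow, and 56060 ± 7725 and 33050 ± 9039 in young and aged bone-associated cells. The 17 macrophage markers summed to 14310 ± 2052, 11770 ± 1440, 30930 ± 2736 and 32100 ± 4919 CPM in the same order. Below, a number given for a gene without a unit is its log2 fold change, or in the interaction the difference between the log2 fold changes.

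The sex-linked transcripts went against the sex label of the aged mice. All samples are labelled male, yet Xist, the RNA that silences one X chromosome in female cells (X: 103460366 to 103483254), had 1482 to 15397 counts in each of the 6 aged libraries and 0 in each of the 6 young libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to between 2638 and 8251 counts in young libraries and to at most 3 in an aged library. Xist was at least 12870-fold higher in aged than in young bone marrow libraries and at least 1606-fold higher in aged than in young bone-associated libraries. Ddx3y (Y: 1260771 to 1286629), an RNA helicase, was lower by a ratio of 3163 (95% counting interval 875 to 26130) in aged bone marrow and at least 1882-fold lower in aged bone-associated cells. Eif2s3y was at least 2444-fold lower in aged bone marrow and lower by a ratio of 4225 (interval 758 to 166900) in aged bone-associated cells. Uty was lower by a ratio of 2473 (interval 444 to 97710) and at least 634-fold lower at the 2 sites, and Kdm5d by a ratio of 1995 (interval 358 to 78830) and at least 325-fold. No age group held both patterns, so age and this difference could not be fitted apart.

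**Figure D1:**
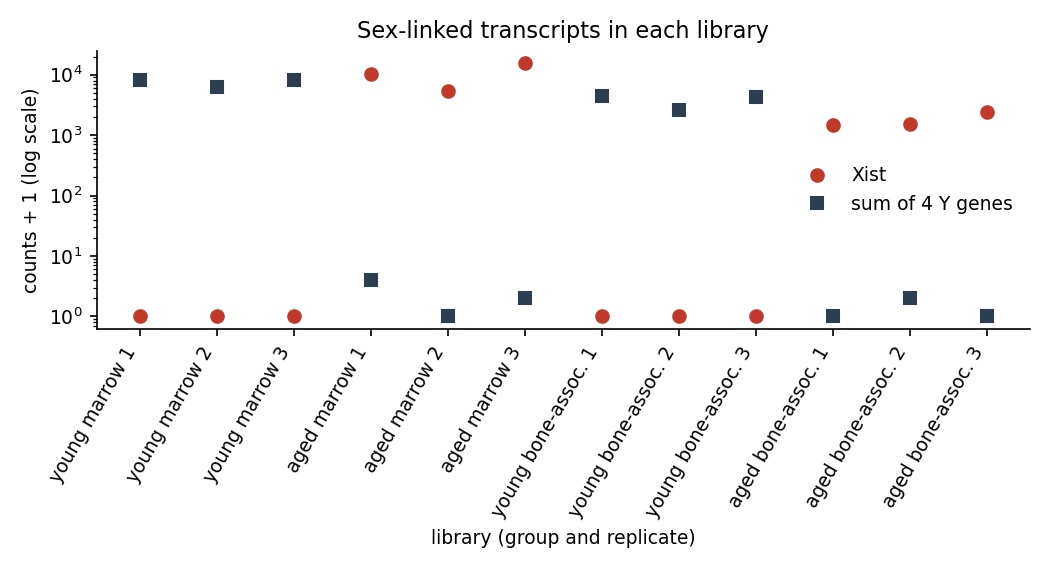
Counts plus 1 on a log axis for Xist (circles) and for the sum of 4 Y-linked genes (squares) in each of the 12 libraries, named by group and replicate. Xist is at 0 in the 6 young libraries and between 1482 and 15397 in the 6 aged ones, and the Y-linked sum runs the other way.

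In the sorted bone marrow cells of the aged mice, most genes listed for macrophages that attend red cell formation were lower, and Il1b and other inflammatory genes were higher. Vcam1, an adhesion molecule of marrow macrophages, was at 1386 ± 238 CPM in young and 198 ± 43.0 in aged libraries (SD, n = 3; log2 fold change -2.81, SE 0.21, adjusted p = 2.28e-05). Cd163, the receptor for haemoglobin bound to haptoglobin, went from 199 ± 19.8 to 17 ± 8.39 CPM (log2 fold change -3.55, SE 0.38, adjusted p = 2.27e-04). Il1b, which encodes the cytokine interleukin-1 beta, went from 173 ± 40.4 to 656 ± 34.4 CPM (log2 fold change 1.92, SE 0.17, adjusted p = 9.51e-05). H2-K1, a class I MHC heavy chain, went from 1112 ± 52.5 to 2147 ± 167 CPM. By position in GRCm38, Vcam1 lies on chromosome 3 (116109949 to 116129688), Cd163 on 6 (124304656 to 124330527), Il1b on 2 (129364570 to 129371139) and H2-K1 on 17 (33996017 to 34000347).

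In this comparison 709 genes were called higher and 500 lower, 7.46% of those tested. The groups' libraries did not overlap for 31.8% of genes, against 10% by chance. Scaling by library size alone changed the share of higher calls from 58.6% to 41.2%. With limma-voom 3252 genes were called and with DESeq2 2094. The count of 1209 calls fell to 608 without young bone marrow replicate 2, 575 without young replicate 3, 738 without aged replicate 1 and 632 without aged replicate 3.

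Of 18 genes of the erythroblastic island and haem iron list, 11 fell and 2 rose (4 higher and 11 lower when adjusted over the list alone), with a median log2 fold change of -1.0. The camera adjusted p was 5.32e-05, and the adjusted p = 0.18 with an estimated correlation. The summed level of the list, which its most abundant genes set, was not lower, at 9683 ± 1482 CPM in young and 10930 ± 2014 CPM in aged libraries. Beside Vcam1 and Cd163, the iron exporter gene Slc40a1 fell by 2.05 on the log2 scale (SE 0.20, adjusted p = 1.21e-04), from 1063 ± 218 to 257 ± 61.8 CPM, and Trf, the plasma iron carrier transferrin, fell by 2.48 (SE 0.21). The share of haemoglobin counts was 0.156% ± 0.0406 in young and 0.405% ± 0.266 in aged bone marrow, and the erythroid marker list was not called (adjusted p = 0.702). Siglec1, the sialic acid receptor sialoadhesin, fell by 2.44 (SE 0.33, adjusted p = 9.94e-04). In the phagocytosis and efferocytosis list, 11 of 33 genes fell and 5 rose (12 and 8 adjusted over the list alone), and the list as a whole was not called (adjusted p = 0.0584, and adjusted p = 0.413 with an estimated correlation). Mertk, a receptor kinase for apoptotic cell uptake, fell by 2.24 (SE 0.18, adjusted p = 4.24e-05), Stab2, a scavenger receptor, by 2.33 (SE 0.23), Timd4, a phosphatidylserine receptor, by 3.01 (SE 0.41) and Axl, the relative of Mertk, by 1.01 (SE 0.17), while Abcg1, a cholesterol exporter, rose by 1.81 (SE 0.20).

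Of 27 genes for inflammatory cytokines and NF-kB targets, 11 rose and 1 fell (15 and 2 adjusted over the list alone; camera adjusted p = 5.07e-06). The same list had an adjusted p = 0.18 with an estimated correlation. Socs3, a feedback inhibitor of cytokine receptors, rose by 2.02 (SE 0.22), Nfkbiz, a nuclear IkB family protein, by 1.72 (SE 0.24), Il10, an anti-inflammatory cytokine, by 3.83 (SE 0.42) and Il12b, the p40 chain of interleukin-12, by 7.83 (SE 1.27). In the IL-1 and inflammasome list, 8 of 23 genes rose and 2 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.00152, and adjusted p = 0.18 with an estimated correlation). Pycard, the inflammasome adaptor, rose by 1.96 (SE 0.25) and Myd88, the adaptor of the interleukin-1 receptor, by 1.08 (SE 0.15), while Il18 fell by 2.08 (SE 0.27). Il1a fell by 1.89 (SE 0.44, adjusted p = 0.0213), but its adjusted p was 0.0547 without young bone marrow replicate 1, 0.0663 without young replicate 3, 0.0982 without aged replicate 3, 0.159 with limma-voom and 0.0512 with no low-count filter. Casp1 (log2 fold change 0.61), Nlrp3 (0.45), Tnf (0.65), Il1r1 (-2.47) and Il1rn (-0.03) did not pass. In alternatives, Il1r1 passed with DESeq2 (adjusted p = 0.0171), limma-voom (0.0119) and the fit of the compared groups only (0.0201), Casp1 with DESeq2 (0.0211) and limma-voom (0.0125), and Tnf with limma-voom (0.0292). Of 13 class I MHC presentation genes, 6 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 6.27e-07, and adjusted p = 0.18 with an estimated correlation).

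Of 29 lysosome genes, 6 rose and 1 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.0319, and adjusted p = 0.693 with an estimated correlation). They included Ctsh (1.44, SE 0.18), Ctsz (0.73, SE 0.14) and Sqstm1 (0.55, SE 0.11), of which Sqstm1 had an adjusted p of 0.0616 without young bone marrow replicate 2. In the list of Ly6C-low monocyte markers, 4 of 11 rose and 0 fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.0126, and adjusted p = 0.413 with an estimated correlation). The median of 0.10 became -0.03 with scaling by library size alone. Cd300e rose by 4.13 and Spn, the sialophorin gene, by 0.56. Of the identity genes, Adgre1, which encodes F4/80, rose by 0.82 (SE 0.15, adjusted p = 0.00619), and Itgam (0.02), Csf1r (0.00), Cd68 (-0.02), Ly6c2 (0.08) and Ly6c1 (0.04) did not pass. The macrophage marker list, with 2 of 17 higher and 5 lower (3 and 5 adjusted over the list alone), was not called (adjusted p = 0.115).

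Genes of cholesterol biosynthesis fell, with 5 of 21 lower and 0 higher (9 and 0 adjusted over the list alone; camera adjusted p = 7.35e-07, and adjusted p = 0.154 with an estimated correlation), among them Sqle, squalene epoxidase (-1.59). Of 38 cell cycle genes, 4 fell and 0 rose (14 and 0 adjusted over the list alone; camera adjusted p = 1.42e-07, and adjusted p = 0.522 with an estimated correlation). In the alternative activation list 3 of 16 fell and 2 rose (5 and 2 adjusted over the list alone; camera adjusted p = 0.0394, and adjusted p = 0.656 with an estimated correlation). Mrc1, the mannose receptor, was at -2.50 and Igf1 at -2.31. For oxidative phosphorylation, 1 of 31 genes fell, Sdhc (-0.50), and 0 rose (0 and 0 adjusted over the list alone; camera adjusted p = 0.0047, and adjusted p = 0.656 with an estimated correlation). Stem and progenitor markers fell in 5 of 12 genes and rose in 0 (10 and 0 adjusted over the list alone; camera adjusted p = 2.56e-06, and adjusted p = 0.154 with an estimated correlation). Cd34 was at -2.64 and Flt3 at -2.09. Osteoblast and stromal markers fell in 5 of 19 and rose in 0 (7 and 0 adjusted over the list alone; camera adjusted p = 2.23e-04, and adjusted p = 0.21 with an estimated correlation). Col1a1, a type I collagen chain, was at -2.36. Osteoclast markers fell in 5 of 12 and rose in 2 (6 and 2 adjusted over the list alone; camera adjusted p = 0.0047, and adjusted p = 0.413 with an estimated correlation). Ctsk, a bone matrix protease, was at -4.28 and Acp5 at 1.20. Endothelial markers fell in 3 of 13 and rose in 0 (3 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.047, and adjusted p = 0.656 with an estimated correlation).

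At the extremes beside the sex-linked genes, Adamdec1, a metalloproteinase-like gene of macrophages, was at 0.889 ± 0.343 CPM in young and 236 ± 161 in aged bone marrow (log2 fold change 8.06, SE 0.95, adjusted p = 4.09e-04). Cxcl13, a B cell attractant, was at least 360.0-fold higher with age, Serpinb1c at least 437-fold and Lhx8 at least 389.5-fold, and Grhl3 was higher by a ratio of 482 (95% counting interval 165 to 2342). Cxcl13 had an adjusted p of 0.0576 and Grhl3 of 0.0639 without young bone marrow replicate 2, and 0.0622 and 0.0703 without young replicate 3, and Cxcl13 of 0.104 with no low-count filter. The C-type lectin genes Cd209f and Cd209g, which belong to one family, both fell by 6.69 (SE 0.60 and 1.08). Counts of immunoglobulin genes made up 0.339% ± 0.0109 of young and 1.15% ± 0.529 of aged bone marrow libraries. Igkc, the kappa light chain constant region, rose by 2.52 and Jchain, which joins IgA and IgM units, by 4.13. The B cell list (2 of 16 higher, 0 lower, and 2 higher and 1 lower adjusted over the list alone; adjusted p = 0.545) and the plasma cell list (2 of 6 higher, 0 lower, the same adjusted over the list alone; adjusted p = 0.0667) were not called.

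In the sorted bone-associated cells of the aged mice, most erythroblastic island genes were lower too, and antigen presentation, stress and inflammatory genes were higher. Vcam1 went from 2724 ± 236 to 504 ± 115 CPM (SD, n = 3; log2 fold change -2.43, SE 0.20, adjusted p = 8.56e-05) and Cd163 from 336 ± 81.4 to 61.0 ± 26.5 CPM (-2.46, SE 0.36, adjusted p = 0.00235). Il1b went from 1506 ± 253 to 2590 ± 108 CPM (0.78, SE 0.17, adjusted p = 0.0143), although its adjusted p was 0.0595 without young bone-associated replicate 1. Socs3 went from 263 ± 11.2 to 693 ± 27.9 CPM (1.40, SE 0.21, adjusted p = 0.00275). The immunoglobulin share of counts went from 0.0615% ± 0.0132 to 3.07% ± 0.238.

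There were 792 genes called higher and 789 lower, 9.75% of those tested, and the groups' libraries did not overlap for 27.9% of genes, against 10% by chance. Scaling by library size alone changed the share of higher calls from 50.1% to 32.3%. With DESeq2 2872 genes were called, and 960 in the fit of the compared groups only. The count of 1581 calls fell to 871 without young bone-associated replicate 1, 780 without replicate 2 and 739 without replicate 3.

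The erythroblastic island and haem iron list fell in 10 of 18 genes and rose in 1 (12 and 2 adjusted over the list alone; camera adjusted p = 1.98e-06, and adjusted p = 0.11 with an estimated correlation). Slc40a1 fell by 2.08 (SE 0.20, adjusted p = 1.54e-04), Tfrc, the transferrin receptor, by 1.68 (SE 0.21) and Trf by 1.39 (SE 0.20). Erythroid markers fell in the same libraries, 5 of 19 lower and 0 higher (14 and 0 adjusted over the list alone; camera adjusted p = 1.98e-06, and adjusted p = 0.368 with an estimated correlation), and the haemoglobin share went from 1.27% ± 0.384 to 0.391% ± 0.186. Mertk (-1.74, SE 0.17, adjusted p = 1.87e-04), Siglec1 (-2.24, SE 0.33) and Axl (-1.13, SE 0.18) fell too, and the phagocytosis and efferocytosis list split into 4 of 33 higher and 5 lower (8 and 7 adjusted over the list alone; adjusted p = 0.999). Of 31 oxidative phosphorylation genes, 23 fell and 0 rose (31 and 0 adjusted over the list alone), with a median of -0.55 (camera adjusted p = 6.84e-12, and adjusted p = 0.203 with an estimated correlation). Cyc1, cytochrome c1 of complex III, fell by 0.90 (SE 0.13), from 304 ± 38.4 to 163 ± 11 CPM, and Sdhc, of complex II, by 0.87 (SE 0.13). Atp5b of the ATP synthase was at -0.63 and Uqcrc2 of complex III at -0.69, and without young bone-associated replicate 2 their adjusted p was 0.0510 and 0.0518, and for Uqcrc2 0.0516 without replicate 3. Cell cycle genes fell in 9 of 38 and rose in 0 (21 and 0 adjusted over the list alone; camera adjusted p = 4.31e-09, and adjusted p = 0.375 with an estimated correlation). Cdk1 was at -1.56. The ribosomal protein list was called lower with 0 of 41 single genes called (also 0 adjusted over the list alone), a median of -0.16 and a camera adjusted p of 0.0494, and adjusted p = 0.729 with an estimated correlation.

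For class II MHC, 10 of 11 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 5.1e-08, and adjusted p = 0.203 with an estimated correlation). H2-Oa rose by 2.57 (SE 0.44), H2-DMb2 by 2.96 (SE 0.53) and Cd74, the invariant chain, by 1.39. Ctss, which trims the invariant chain, was at 0.97 (SE 0.20) and the peptide exchange gene H2-DMb1 at 0.87 (SE 0.20). Their adjusted p was 0.0513 and 0.0742 without young bone-associated replicate 1, and 0.0590 and 0.0772 without replicate 3. The B cell markers, which share class II expression, rose in the same libraries in 6 of 16 genes and fell in 1 (10 and 2 adjusted over the list alone; camera adjusted p = 9.31e-04, and adjusted p = 0.403 with an estimated correlation). Cd79a was at 2.44 and Igkc at 8.20. Plasma cell markers rose in 2 of 6, Jchain (11.18, SE 1.04) and Mzb1 (3.77), and fell in 0 (4 and 1 adjusted over the list alone; camera adjusted p = 0.00292, and adjusted p = 0.199 with an estimated correlation). Dendritic cell markers rose in 2 of 10, Ccr7 (2.54) and Batf3 (1.88), and fell in 0 (2 and 0 adjusted over the list alone; camera adjusted p = 0.00701, and adjusted p = 0.252 with an estimated correlation). For class I MHC, 10 of 13 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 2.46e-08, and adjusted p = 0.11 with an estimated correlation). H2-K1 rose by 0.92 (SE 0.11, adjusted p = 5.82e-04), H2-D1 by 0.79 (SE 0.11), the peptide trimming gene Erap1 by 0.73 (SE 0.13) and the peptide transporter gene Tap2 by 0.61 (SE 0.11).

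Inflammatory cytokines and NF-kB targets rose in 11 of 27 genes and fell in 0 (17 and 0 adjusted over the list alone; camera adjusted p = 4.44e-08, and adjusted p = 0.11 with an estimated correlation). Bcl3, an IkB family protein, was at 1.14 (SE 0.21). The NF-kB subunit genes Relb (0.76, SE 0.18) and Rel (0.79, SE 0.19) lost their calls without young bone-associated replicate 1 (adjusted p = 0.0695 and 0.0627), young replicate 3 (0.0816 and 0.0979) or aged replicate 2 (0.0609 and 0.0692), and Rel also without young replicate 2 (0.0592). In the fit of the compared groups only they were at 0.0503 and 0.0818, and Rel at 0.0526 with library size scaling. Chemokines rose in 4 of 22 and fell in 0 (8 and 0 adjusted over the list alone; camera adjusted p = 6.36e-05, and adjusted p = 0.262 with an estimated correlation). Ccl4 was at 1.20 and Ccl3 at 0.94. The IL-1 and inflammasome list rose in 5 of 23 and fell in 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0248, and adjusted p = 0.276 with an estimated correlation). In it Il18 fell by 1.59, and Il1a (0.09), Il1rn (-0.08), Il1r1 (-1.62), Casp1 (0.41), Nlrp3 (0.29) and, of the key genes outside it, Tnf (0.49) did not pass. Heat shock and unfolded protein genes rose in 9 of 22 and fell in 0 (12 and 0 adjusted over the list alone; camera adjusted p = 1.22e-05, and adjusted p = 0.11 with an estimated correlation). Xbp1 was at 0.92 and Hsph1 at 1.62. Immediate early genes rose in 4 of 23 and fell in 0 (10 and 0 adjusted over the list alone; camera adjusted p = 4.06e-05, and adjusted p = 0.283 with an estimated correlation). Nr4a1 was at 0.90. Fc receptor and complement genes rose in 5 of 19 and fell in 2 (6 and 3 adjusted over the list alone; camera adjusted p = 0.0474, and adjusted p = 0.432 with an estimated correlation). Glycolysis and hypoxia genes rose in 5 of 23 and fell in 0 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0494, and adjusted p = 0.472 with an estimated correlation). The median of 0.08 became -0.04 with scaling by library size alone. Ly6C-low monocyte markers rose in 7 of 11 and fell in 0 (10 and 0 adjusted over the list alone; camera adjusted p = 4.25e-07, and adjusted p = 0.11 with an estimated correlation). Spn was at 1.02. Adgre1 (0.31), Csf1r (0.45), Cd68 (-0.07), Itgam (-0.02), Ly6c2 (-0.75) and Ly6c1 (0.57) did not pass. Csf1r passed with DESeq2 (adjusted p = 0.0424), and Ly6c2 with DESeq2 (0.0392) and library size scaling (0.0482). The macrophage marker list, with 1 of 17 higher and 5 lower (2 and 6 adjusted over the list alone), was not called (adjusted p = 0.16, and adjusted p = 0.637 with an estimated correlation).

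Neutrophil markers fell in 9 of 19 and rose in 0 (12 and 0 adjusted over the list alone; camera adjusted p = 4e-05, and adjusted p = 0.358 with an estimated correlation), and the share of counts of 6 neutrophil genes went from 4.62% ± 0.524 to 2.49% ± 0.715. Eosinophil markers fell in 6 of 9 and rose in 0 (6 and 2 adjusted over the list alone; camera adjusted p = 5.96e-04, and adjusted p = 0.11 with an estimated correlation). The granule genes Epx (-5.93, SE 1.07) and Ear6 (-5.96, SE 1.07) were called with edgeR, but with limma-voom their adjusted p was 0.274 and 0.150. Osteoclast markers fell in 7 of 12 and rose in 0 (10 and 0 adjusted over the list alone; camera adjusted p = 1.55e-06, and adjusted p = 0.116 with an estimated correlation). Acp5, tartrate-resistant acid phosphatase, was at -1.09. Osteoblast and stromal markers fell in 2 of 19 and rose in 1 (2 and 1 adjusted over the list alone; camera adjusted p = 0.0168, and adjusted p = 0.358 with an estimated correlation). Megakaryocyte and platelet markers fell in 2 of 17 and rose in 0 (12 and 0 adjusted over the list alone; camera adjusted p = 0.00394, and adjusted p = 0.472 with an estimated correlation). Their summed level was carried by 1 library: it was 2589.5 CPM in young bone-associated replicate 2, 261 and 126 CPM in young replicates 1 and 3, and 104, 137 and 399 CPM in the aged replicates. Without that library the summed level was not lower with age. Among the highest genes, Ctla4, a T cell inhibitory receptor, was at least 222-fold higher with age, Dtx1 rose by 6.70 (SE 0.70) and Fcrl5, an Fc receptor-like gene of B lineage cells, by 6.20 (SE 0.67). Cxcl13 was at 7.32 (SE 1.76, adjusted p = 0.0299), but at an adjusted p of 0.0686, 0.105 and 0.10 without young bone-associated replicates 1, 2 and 3 0.0510 without aged replicate 2 and 0.135 with no low-count filter. The type I interferon list was not called for age at either site (adjusted p = 0.0679 and 0.0801), nor were Ly6C-high monocyte markers (adjusted p = 0.544 and 0.0593).

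**Figure D2:**
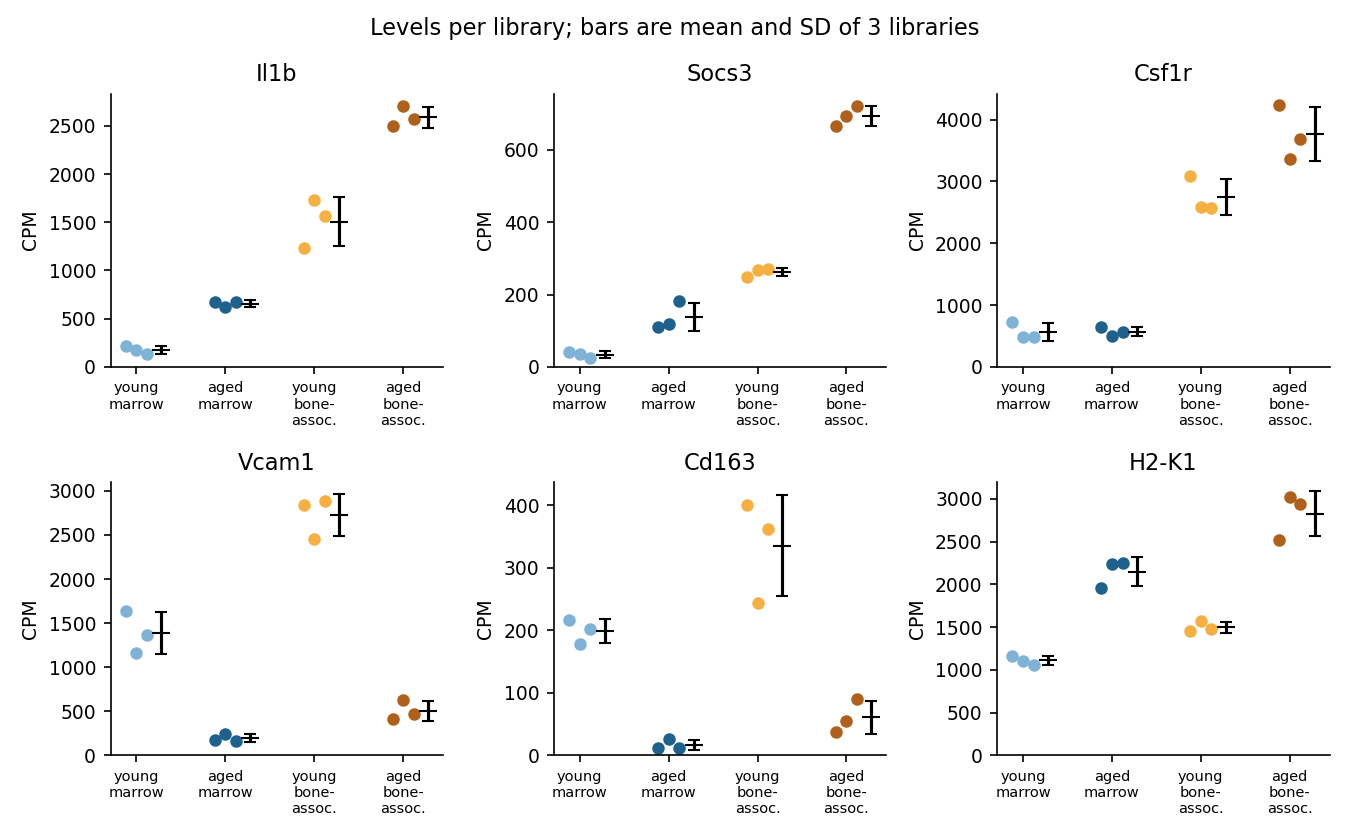
CPM per library (points) with mean and SD of 3 libraries (bars) for Il1b, Socs3, Csf1r, Vcam1, Cd163 and H2-K1 in the 4 groups, each axis starting at 0. Il1b is at 173 ± 40.4, 656 ± 34.4, 1506 ± 253 and 2590 ± 108 CPM in young marrow, aged marrow, young bone-associated and aged bone-associated libraries, while Vcam1 is lower with age at both sites.

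The age effects at the 2 sites overlapped. Of the genes called higher with age, 301 were shared, against 34.6 for independent lists (odds ratio 22.5, two-sided Fisher's exact p = 5.2e-220), and of those called lower 175 were shared, against 24.3 (odds ratio 13.2, p = 1.7e-105). Genes are not independent, and 10 genes were called in opposite directions. Across genes the fold changes correlated with Pearson's r of 0.38 and Spearman's rho of 0.36, as a description. The sites share mice, the sex-linked difference and the fit, so part of the excess may come from these. The shared set included Vcam1, Slc40a1, Mertk, Siglec1, Cd163, Axl, Socs3 and H2-K1 in the direction given above.

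The difference between the age effects at the 2 sites was called for 45 genes with edgeR, with B lineage transcripts among the largest. With DESeq2 673 genes were called, all 45 among them, and in simulations edgeR recovered 7.07% of 2-fold differences, so the number is not an estimate of how many genes differ. Jchain (chromosome 5, 88519809 to 88527891) went from 21.0 ± 15.5 to 369 ± 188 CPM with age in bone marrow and from 0.612 ± 0.486 to 1459 ± 304 CPM in bone-associated cells (interaction 7.04, SE 1.10, adjusted p = 0.0374). Its adjusted p was 0.254 with limma-voom and 0.0983 with no low-count filter, and its call was lost in 9 of the 12 fits without 1 library, all but those without young bone marrow replicate 2, aged bone marrow replicate 2 or aged bone-associated replicate 1. Igkc (5.67, SE 0.69) and Ighm (3.02, SE 0.42), the constant regions of the kappa light and mu heavy chains, also rose more with age in bone-associated cells. Acp5 (chromosome 9, 22126727 to 22135711) went from 275 ± 64.5 to 632 ± 275 CPM in bone marrow and from 1768 ± 200 to 828 ± 153 CPM in bone-associated cells (interaction -2.29, SE 0.39, adjusted p = 0.0374). Il10 went from 1.44 ± 0.752 to 20.6 ± 6.66 CPM and from 19.7 ± 2.46 to 30.4 ± 6.95 CPM (interaction -3.20, SE 0.54). Cdkn1a, the cell cycle inhibitor p21, was at 23.9 ± 0.152 and 21.6 ± 3.05 CPM in bone marrow and at 293 ± 71.0 and 663 ± 6.74 CPM in bone-associated cells (interaction 1.33, SE 0.22).

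In all, 32 genes were called with a higher and 13 with a lower age effect in bone-associated cells. With the mouse as a replicate block the count was 57, of which 22 were shared with the 45, and the adjusted p was 0.0766 for Gzma, 0.0518 for Acp5, 0.0801 for Fnbp1l, 0.0544 for Fblim1 and 0.0504 for Cdkn1a. The count was 12, 1 and 0 without young bone marrow replicates 1, 2 and 3, and 8, 170 and 4 without those of aged bone marrow. It was 0, 4 and 0 without those of young bone-associated cells, and 131, 48 and 25 without those of aged bone-associated cells. The other named genes were Dtx1 (5.83), Lax1 (4.24), Fgfr1 (4.18), Afap1l1 (3.72), Map7 (3.34), Flt3 (3.11), Plac8 (1.64), Grap2 (-2.62), Fnbp1l (-2.28) and Fblim1 (-2.10). Gzma had no count in aged bone-associated libraries, where it was at least 134-fold lower with age, and went from 34.1 ± 6.77 to 8.98 ± 3.29 CPM in bone marrow, so the size of its interaction was not measured. With limma-voom the adjusted p was 0.0529 for Lax1, 0.0532 for Fgfr1, 0.135 for Afap1l1, 0.0739 for Map7, 0.192 for Gzma and 0.0539 for Grap2, and with no low-count filter it was 0.0763 for Flt3. Every gene named here lost its call in 4 to 10 of the 12 fits without 1 library. Il1b had an interaction of -1.14 (SE 0.24, adjusted p = 0.0725), and 0.00106 with DESeq2 and 0.0303 with no low-count filter. Il1a (1.98) passed with DESeq2 only (adjusted p = 0.0257). Vcam1 (0.38), Cd163 (1.09), Mertk (0.50), Siglec1 (0.20), Axl (-0.12), Csf1r (0.45), Adgre1 (-0.51), Tnf (-0.16), Nlrp3 (-0.15), Casp1 (-0.20), Il1rn (-0.06), Il1r1 (0.85), Itgam (-0.04), Cd68 (-0.05), Ly6c1 (0.53) and Ly6c2 (-0.83) did not pass.

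Among the lists, the age effect was higher in bone-associated cells for class II MHC presentation (median 1.14, 0 of 11 called, 2 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.29e-05, and adjusted p = 0.409 with an estimated correlation). The same held for alternative activation (median 1.60, 0 of 16 called, 9 and 1 adjusted over the list alone; camera adjusted p = 8.99e-05, and adjusted p = 0.409 with an estimated correlation). Heat shock and unfolded protein genes (median 0.53, 0 of 22 called, 9 and 0 adjusted over the list alone) had a camera adjusted p of 7.61e-05, and adjusted p = 0.18 with an estimated correlation. Cholesterol biosynthesis (median 0.41, 0 of 21 called, 1 and 0 adjusted over the list alone) had 0.00457, and adjusted p = 0.409 with an estimated correlation. Immediate early genes (median 0.26, 0 of 23 called, 2 and 0 adjusted over the list alone) had 0.0245, and adjusted p = 0.581 with an estimated correlation. B cell markers (2 of 16 higher, 7 and 0 adjusted over the list alone) had 1.29e-05, and adjusted p = 0.409 with an estimated correlation. Dendritic cell markers (1 of 10 higher, 7 and 0 adjusted over the list alone) had 7.61e-05, and adjusted p = 0.195 with an estimated correlation. Stem and progenitor markers (1 of 12 higher, 6 and 0 adjusted over the list alone) had 2.42e-06, and adjusted p = 0.127 with an estimated correlation.

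The age effect was lower in bone-associated cells for oxidative phosphorylation (median -0.37, 0 of 31 called, 0 adjusted over the list alone; camera adjusted p = 1.29e-05, and adjusted p = 0.482 with an estimated correlation). Ribosomal proteins (median -0.17, 0 of 41 called, 0 adjusted over the list alone) had a camera adjusted p of 0.0264, adjusted p = 0.716 with an estimated correlation, and 0.0623 with the replicate block. Neutrophil markers (0 of 19 called, 6 lower adjusted over the list alone) had 7.66e-04, and adjusted p = 0.571 with an estimated correlation. Eosinophil markers (0 of 9 called, 3 lower adjusted over the list alone) had 0.0236, and adjusted p = 0.211 with an estimated correlation. Erythroid markers (0 of 19 called, 6 lower adjusted over the list alone) had 1.77e-04, and adjusted p = 0.571 with an estimated correlation. With the replicate block, chemokines (adjusted p = 0.0739) passed at 0.00743, and basophil and mast cell markers (0.0911) and plasma cell markers (0.054) at 0.0492 each.

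**Figure D3:**
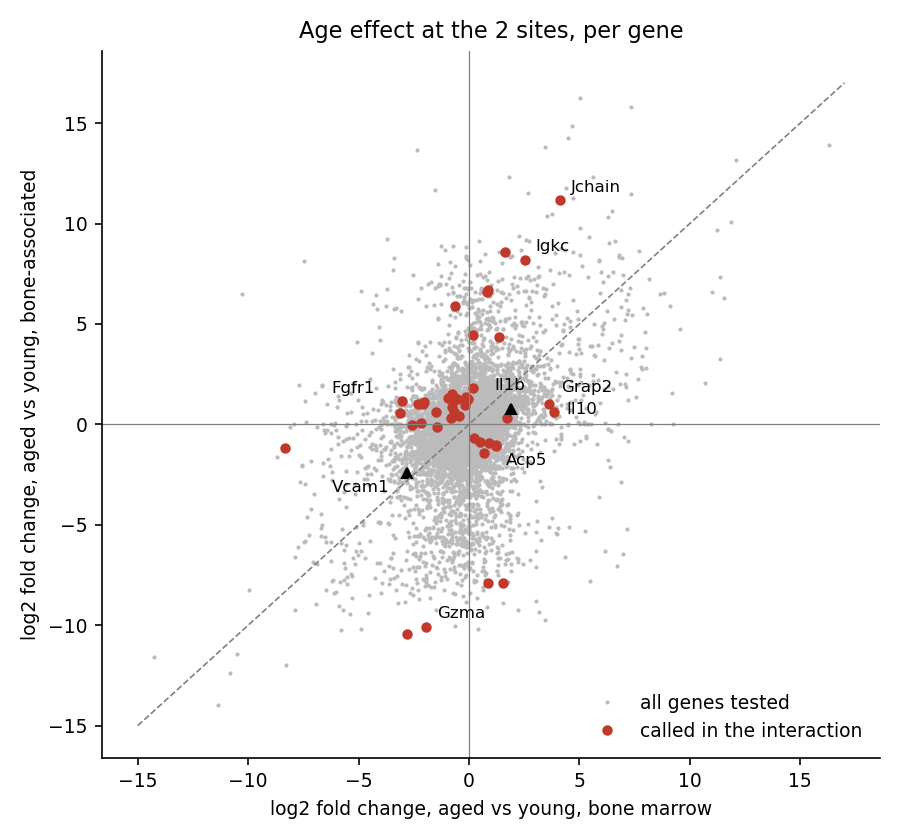
Log2 fold change with age in bone marrow (horizontal) against that in bone-associated cells (vertical) for each gene tested (grey), with the 45 genes called in the interaction in red, Vcam1 and Il1b as triangles and a dashed line of equal change. Across genes r is 0.38, and Jchain and Igkc lie far above the line while Il10, Grap2 and Acp5 lie below it.

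In young mice, sorted cells of the bone-associated fraction held more macrophage, lysosome and inflammatory transcripts than those of bone marrow. Csf1r, the receptor for macrophage colony-stimulating factor (chromosome 18, 61100598 to 61132149), was at 567 ± 142 CPM in bone marrow and 2747 ± 298 in bone-associated libraries (SD, n = 3; log2 fold change 2.28, SE 0.18, adjusted p = 1.04e-05). Il1b was at 173 ± 40.4 and 1506 ± 253 CPM (3.12, SE 0.18, adjusted p = 1.33e-06). Tgm2, tissue transglutaminase (chromosome 2, 158116402 to 158146436), was at 46.4 ± 4.80 and 419 ± 26.9 CPM (3.18, SE 0.18, adjusted p = 1.18e-06). Markers of B, T and NK, and stem and progenitor cells were lower, and erythroid, osteoclast and stromal markers higher, in the bone-associated libraries.

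In this comparison 2423 genes were called higher and 2100 lower in bone-associated cells, 27.9% of those tested, and the groups' libraries did not overlap for 53.3% of genes, against 10% by chance. With limma-voom 7209 genes were called. Scaling by library size alone changed the share of higher calls from 53.6% to 22.0%.

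The lysosome list rose in 26 of 29 genes and fell in 0 (26 and 0 adjusted over the list alone; camera adjusted p = 6.74e-15, and adjusted p = 0.0974 with an estimated correlation). Sqstm1, an autophagy receptor, was higher by 2.15 (SE 0.12), the proton pump subunits Atp6v1b2 by 2.01 (SE 0.13) and Atp6v1a by 2.05 (SE 0.14), and Gla, alpha-galactosidase, by 1.85 (SE 0.15). Phagocytosis and efferocytosis rose in 18 of 33 and fell in 0 (24 and 0 adjusted over the list alone; camera adjusted p = 1.05e-08, and adjusted p = 0.0508 with an estimated correlation). Itgav (2.13, SE 0.20), Rac1 (0.95, SE 0.09) and Havcr2 (1.44, SE 0.17) were higher. Axl was higher by 1.27 (SE 0.18), while Mertk (0.07) did not pass. Fc receptor and complement genes rose in 10 of 19 and fell in 0 (12 and 0 adjusted over the list alone; camera adjusted p = 2.92e-05, and adjusted p = 0.143 with an estimated correlation). Macrophage markers rose in 10 of 17 and fell in 0 (10 and 0 adjusted over the list alone; camera adjusted p = 1.96e-05, and adjusted p = 0.143 with an estimated correlation). Adgre1 was at 2.01 (SE 0.16) and Cd68 at 1.41 (SE 0.17). Ly6C-low monocyte markers rose in 7 of 11 and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.00146, and adjusted p = 0.178 with an estimated correlation). The gene of CD11b itself, Itgam, was at 0.51 (adjusted p = 0.0381) and lost its call without any of the young bone marrow replicates (0.0937, 0.122 and 0.0805), without young bone-associated replicates 1 and 3 (0.169 and 0.0711) and with library size scaling (0.626). Cd163 (0.76) passed only with limma-voom (adjusted p = 0.00377) and in the fit of the compared groups only (0.0123), Siglec1 (0.30), Ly6c1 (2.35) and Ly6c2 (-0.24) did not pass, and Vcam1 was higher by 0.97 (SE 0.19). The erythroblastic island and haem iron list rose in 11 of 18 and fell in 0 (12 and 0 adjusted over the list alone; camera adjusted p = 5.51e-06, and adjusted p = 0.0823 with an estimated correlation). Erythroid markers rose in the same libraries in 16 of 19 and fell in 0 (18 and 0 adjusted over the list alone; camera adjusted p = 3.54e-10, and adjusted p = 0.178 with an estimated correlation), and the haemoglobin share was 0.156% ± 0.0406 in bone marrow and 1.27% ± 0.384 in bone-associated libraries.

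Inflammatory cytokines and NF-kB targets rose in 18 of 27 genes and fell in 1 (22 and 1 adjusted over the list alone; camera adjusted p = 1.05e-08, and adjusted p = 0.0823 with an estimated correlation). Tnfaip3 (2.19, SE 0.16) and Nfkbia (1.80, SE 0.15), feedback inhibitors of NF-kB, Socs3 (2.96, SE 0.23) and Rel (2.03, SE 0.20) were higher. Immediate early genes rose in 14 of 23 and fell in 4 (15 and 4 adjusted over the list alone; camera adjusted p = 2.92e-05, and adjusted p = 0.178 with an estimated correlation). Atf3 was at 2.86, Fosb at 3.62, Maff at 2.65 and Nr4a3 at 3.22. Chemokines rose in 13 of 22 and fell in 2 (14 and 2 adjusted over the list alone; camera adjusted p = 4.17e-04, and adjusted p = 0.198 with an estimated correlation). Their median of 2.28 became 1.91 with genes at 0 set to their bound, and the monocyte attractants Ccl2 (4.55) and Ccl7 (5.37, SE 0.87) were higher. The IL-1 and inflammasome list rose in 9 of 23 and fell in 2 (the same adjusted over the list alone; camera adjusted p = 0.0138, and adjusted p = 0.178 with an estimated correlation). The median of 0.23 became -0.17 with scaling by library size alone. In it Il1a (2.92, SE 0.43), the receptor antagonist gene Il1rn (2.48, SE 0.26) and Nlrp3 (2.02, SE 0.26) were higher, and Casp1 (-0.10) and Il1r1 (-1.73) did not pass, though Il1r1 did with limma-voom (adjusted p = 0.00489) and in the fit of the compared groups only (0.0418). Tnf was at 1.06 (adjusted p = 0.0118), with an adjusted p of 0.0560 without young bone-associated replicate 2 and 0.0763 with library size scaling. Heat shock and unfolded protein genes rose in 11 of 22 and fell in 1 (12 and 2 adjusted over the list alone; camera adjusted p = 1.18e-04, and adjusted p = 0.0823 with an estimated correlation).

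Oxidative phosphorylation rose in 23 of 31 and fell in 0 (24 and 0 adjusted over the list alone; camera adjusted p = 2.81e-11, and adjusted p = 0.163 with an estimated correlation). The complex III genes Uqcrc1 (1.27) and Uqcrfs1 (1.16) and the ATP synthase genes Atp5a1 (1.16) and Atp5b (1.27) were higher. Glycolysis and hypoxia rose in 14 of 23 and fell in 0 (17 and 1 adjusted over the list alone; camera adjusted p = 2.07e-07, and adjusted p = 0.0974 with an estimated correlation). The glucose transporter gene Slc2a1 was at 2.01. Cholesterol biosynthesis rose in 7 of 21 and fell in 0 (the same adjusted over the list alone; camera adjusted p = 0.00539, and adjusted p = 0.178 with an estimated correlation). Alternative activation rose in 9 of 16 and fell in 0 (11 and 0 adjusted over the list alone; camera adjusted p = 1.79e-04, and adjusted p = 0.178 with an estimated correlation). Lyve1, a hyaluronan receptor, was at 3.45. Senescence and secreted remodelling factors rose in 8 of 17 and fell in 0 (the same adjusted over the list alone; camera adjusted p = 8.43e-06, and adjusted p = 0.0508 with an estimated correlation). Cdkn1a was at 3.61. Factors acting on haematopoietic stem cells rose in 9 of 22 and fell in 2 (the same adjusted over the list alone; camera adjusted p = 0.00893, and adjusted p = 0.0974 with an estimated correlation). Spp1, osteopontin, was at 3.09 and Angpt1 at -3.29.

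Of the other cell types, osteoclast markers rose in 10 of 12 and fell in 0 (11 and 0 adjusted over the list alone; camera adjusted p = 1.98e-07, and adjusted p = 0.0823 with an estimated correlation). Osteoblast and stromal markers rose in 6 of 19 and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00165, and adjusted p = 0.178 with an estimated correlation). B cell markers fell in 11 of 16 and rose in 0 (15 and 0 adjusted over the list alone; camera adjusted p = 1.8e-06, and adjusted p = 0.178 with an estimated correlation). Pax5 was at -3.90. T and NK cell markers fell in 13 of 21 and rose in 0 (15 and 1 adjusted over the list alone; camera adjusted p = 1.5e-04, and adjusted p = 0.143 with an estimated correlation). Stem and progenitor markers fell in 9 of 12 and rose in 0 (the same adjusted over the list alone; camera adjusted p = 2.92e-05, and adjusted p = 0.0823 with an estimated correlation). Myb was at -3.06. Basophil and mast cell markers fell in 4 of 8 and rose in 0 (the same adjusted over the list alone; camera adjusted p = 0.0455, and adjusted p = 0.571 with an estimated correlation). Dendritic cell markers (adjusted p = 0.0525) passed at 0.0453 with the replicate block, and megakaryocyte and platelet markers (adjusted p = 0.0827), whose summed level was highest in young bone-associated replicate 2, at 0.0264. At the extremes, Flrt3 was at least 526-fold higher in bone-associated cells, with an adjusted p of 0.0579 with no low-count filter, and Gprc5a was higher by 6.72 (SE 0.82), Lrrc32 by 6.01 (SE 1.37), Wnt11 by 5.80 (SE 1.33) and Retnla by 6.35 (SE 1.45, adjusted p = 0.118 with limma-voom). Efcc1 was at least 255-fold lower, Nkx2-3 lower by a ratio of 530 (95% counting interval 147 to 4381), and Bzrap1 (-7.60), Fam129c (-5.28), Lax1 (-5.03) and Jchain (-5.06, adjusted p = 0.156 with limma-voom) were lower.

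In aged mice, macrophage, lysosome and NF-kB target genes were higher in the bone-associated cells. Csf1r was at 568 ± 75.8 CPM in bone marrow and 3761 ± 438 in bone-associated libraries (SD, n = 3; log2 fold change 2.73, SE 0.19, adjusted p = 2.56e-06). Il1b was at 656 ± 34.4 and 2590 ± 108 CPM (1.98, SE 0.17, adjusted p = 1.13e-05) and Tgm2 at 66.3 ± 11.5 and 706 ± 142 CPM (3.41, SE 0.18, adjusted p = 8.95e-07). Cd36, a scavenger receptor, was at 42.5 ± 17.9 and 772 ± 257 CPM (4.18, SE 0.36, adjusted p = 1.08e-05). Neutrophil markers were lower in bone-associated libraries, and Slfn4 fell from 367 ± 23.4 to 9.95 ± 0.905 CPM.

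There were 2701 genes called higher and 2718 lower in bone-associated cells, 33.4% of those tested, and the groups' libraries did not overlap for 46.1% of genes, against 10% by chance. Scaling by library size alone changed the share of higher calls from 49.8% to 22.1%.

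Phagocytosis and efferocytosis rose in 24 of 33 genes and fell in 0 (25 and 0 adjusted over the list alone), with a camera adjusted p of 6.12e-10 that stayed below the threshold with an estimated correlation (adjusted p = 0.0296). Gas6, the bridging ligand of Mertk and Axl, was higher by 4.74 (SE 0.42), Havcr2 by 2.05 (SE 0.17) and Axl by 1.15 (SE 0.18). Mertk was at 0.58 (adjusted p = 0.0226), with 0.0735 without aged bone marrow replicate 2, 0.0866 without aged bone-associated replicate 1, 0.403 with library size scaling, 0.0922 with limma-voom and 0.0646 in the fit of the compared groups only. Heat shock and unfolded protein genes rose in 15 of 22 and fell in 0 (16 and 0 adjusted over the list alone), and this call too held with an estimated correlation (camera adjusted p = 3.02e-08, and adjusted p = 0.0343 with an estimated correlation). Hspa5, an endoplasmic reticulum chaperone, was at 1.77 and Hsph1 at 3.68. The lysosome list rose in 22 of 29 and fell in 1 (23 and 1 adjusted over the list alone; camera adjusted p = 2.86e-10, and adjusted p = 0.142 with an estimated correlation). Sqstm1 was at 2.16 (SE 0.12), Gla at 2.19 (SE 0.15), Atp6v1b2 at 1.45 (SE 0.12) and the peptidase gene Tpp1 at 1.33 (SE 0.11). Inflammatory cytokines and NF-kB targets rose in 17 of 27 and fell in 1 (the same adjusted over the list alone; camera adjusted p = 6.11e-08, and adjusted p = 0.102 with an estimated correlation). Tnfaip3 was at 2.22, the costimulatory gene Cd86 at 2.18, Socs3 at 2.34 and the adhesion molecule gene Icam1 at 2.49. Chemokines rose in 13 of 22 and fell in 1 (16 and 1 adjusted over the list alone; camera adjusted p = 1.44e-05, and adjusted p = 0.158 with an estimated correlation). Immediate early genes rose in 14 of 23 and fell in 2 (the same adjusted over the list alone; camera adjusted p = 3.42e-07, and adjusted p = 0.142 with an estimated correlation). Nr4a2 was at 5.74. The IL-1 and inflammasome list was not called (7 of 23 higher and 5 lower, 8 and 5 adjusted over the list alone; adjusted p = 0.0928), although Il1a (4.90, SE 0.48), Il1rn (2.43, SE 0.26) and Nlrp3 (1.87, SE 0.26) were higher. Casp1 (-0.30, and adjusted p = 0.0106 with library size scaling) and Il1r1 (-0.88) did not pass.

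Class II MHC presentation rose in 7 of 11 and fell in 0 (the same adjusted over the list alone; camera adjusted p = 0.0016, and adjusted p = 0.346 with an estimated correlation). Cd74 was at 2.08. The immunoglobulin share was 1.15% ± 0.529 in aged bone marrow and 3.07% ± 0.238 in aged bone-associated libraries. Alternative activation rose in 12 of 16 and fell in 0 (13 and 1 adjusted over the list alone; camera adjusted p = 8.62e-07, and adjusted p = 0.141 with an estimated correlation). Lyve1 was at 6.66, Folr2 at 5.27 and Mrc1 at 1.97. Fc receptor and complement genes rose in 9 of 19 and fell in 1 (the same adjusted over the list alone; camera adjusted p = 0.00153, and adjusted p = 0.227 with an estimated correlation). The erythroblastic island and haem iron list rose in 11 of 18 and fell in 2 (the same adjusted over the list alone; camera adjusted p = 9.7e-05, and adjusted p = 0.116 with an estimated correlation). Cd163 was at 1.85 (SE 0.36) and Vcam1 at 1.35 (SE 0.20). Erythroid markers rose in 11 of 19 and fell in 0 (13 and 0 adjusted over the list alone; camera adjusted p = 3.1e-05, and adjusted p = 0.346 with an estimated correlation). Macrophage markers rose in 11 of 17 and fell in 0 (the same adjusted over the list alone; camera adjusted p = 8.74e-06, and adjusted p = 0.141 with an estimated correlation). Adgre1 was at 1.50 (SE 0.15) and Cd68 at 1.36 (SE 0.17). Ly6C-low monocyte markers rose in 7 of 11 and fell in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 3.93e-04, and adjusted p = 0.169 with an estimated correlation). Ly6c2 was lower, at -1.07 (SE 0.26), and Siglec1 (0.50, and adjusted p = 0.0268 without aged bone-associated replicate 1) and Ly6c1 (2.87) did not pass. Itgam was at 0.47 (adjusted p = 0.0466, and 0.716 with library size scaling) and lost its call without aged bone marrow replicates 1 and 3 (0.133 and 0.135) and each aged bone-associated replicate (0.0694, 0.108 and 0.102). It also lost it with no low-count filter (0.0537), the 5 CPM filter (0.0509), the compared groups only (0.0754) and without immunoglobulin genes and other markers (0.0505). Tnf was at 0.90 (adjusted p = 0.0225), with 0.0735 and 0.0803 without aged bone marrow replicates 2 and 3 and 0.0582 and 0.0593 without aged bone-associated replicates 2 and 3, and 0.154 with library size scaling.

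Glycolysis and hypoxia rose in 17 of 23 and fell in 0 (the same adjusted over the list alone; camera adjusted p = 1.31e-08, and adjusted p = 0.102 with an estimated correlation). Oxidative phosphorylation rose in 16 of 31 and fell in 1 (18 and 2 adjusted over the list alone; camera adjusted p = 1.18e-04, and adjusted p = 0.346 with an estimated correlation). Uqcrfs1 was at 1.04, Atp5b at 1.04, Uqcrc1 at 1.00 and Atp5a1 at 0.92. Cholesterol biosynthesis rose in 10 of 21 and fell in 0 (13 and 0 adjusted over the list alone; camera adjusted p = 1.99e-05, and adjusted p = 0.102 with an estimated correlation). Senescence and secreted remodelling factors rose in 9 of 17 and fell in 0 (10 and 0 adjusted over the list alone; camera adjusted p = 1.2e-04, and adjusted p = 0.0801 with an estimated correlation). Cdkn1a was at 4.94. Factors acting on haematopoietic stem cells rose in 9 of 22 and fell in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00197, and adjusted p = 0.095 with an estimated correlation). Ribosomal proteins fell in 19 of 41 and rose in 0 (20 and 1 adjusted over the list alone; camera adjusted p = 0.037, adjusted p = 0.684 with an estimated correlation, and 0.0753 with the replicate block), with Rps27 (-0.98), Rpl12 (-0.77), Rpl32 (-0.67) and Rpl37 (-0.60). Osteoclast markers rose in 6 of 12 and fell in 0 (7 and 0 adjusted over the list alone; camera adjusted p = 9.7e-05, and adjusted p = 0.142 with an estimated correlation), and osteoblast and stromal markers in 10 of 19 with 0 lower (11 and 0 adjusted over the list alone; camera adjusted p = 1.2e-04, and adjusted p = 0.141 with an estimated correlation). Neutrophil markers fell in 10 of 19 and rose in 0 (12 and 0 adjusted over the list alone; camera adjusted p = 3.93e-04, and adjusted p = 0.346 with an estimated correlation). S100a8 was at -1.92. T and NK cell markers fell in 6 of 21 and rose in 1 (the same adjusted over the list alone; camera adjusted p = 0.0092, and adjusted p = 0.263 with an estimated correlation). At the extremes, Flrt3 was at least 3406-fold, Gprc5a at least 773-fold and Ednrb at least 490-fold higher, and Fcrls (9.66, SE 0.90), Fxyd2 (7.30, SE 1.02) and Retnla (9.80, SE 1.73, adjusted p = 0.120 with limma-voom) were higher. Pde1b (-8.02), Nlrp1c-ps (-5.44), Dennd6b (-5.30), Epx (-6.55, adjusted p = 0.147 with limma-voom) and Ear6 (-6.49, adjusted p = 0.0650 with limma-voom) were lower.

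**Figure D4:**
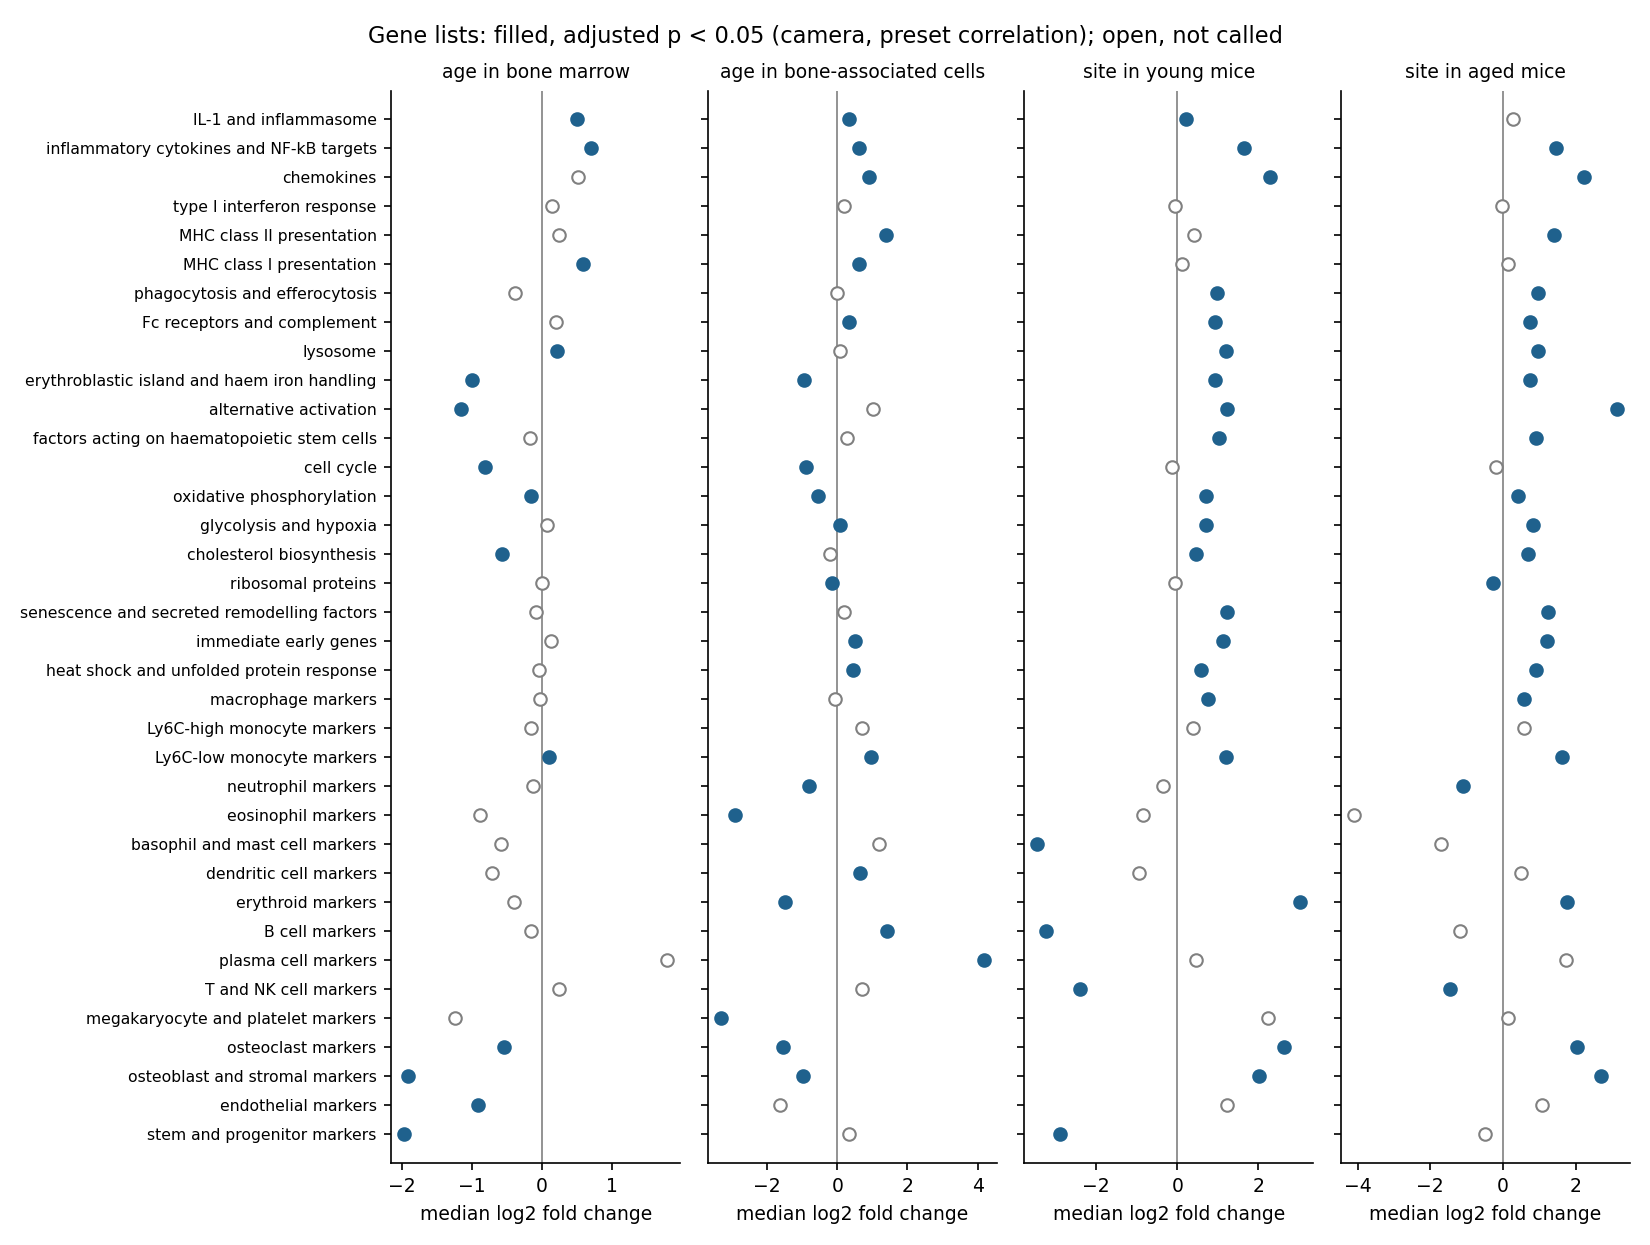
Median log2 fold change of each of the 36 gene lists (one line per list) in the 2 age and the 2 site comparisons, filled where camera with the preset correlation gave an adjusted p below the threshold and open otherwise. Filled points number 14, 23, 24 and 23 from left to right, and the erythroblastic island list is lower with age at both sites.

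The site effect was shared between the ages for 1771 genes called higher and 1292 called lower, against 404 and 352 for independent lists (odds ratios 37.5 and 14.2, two-sided Fisher's exact test, p below what could be stored). In opposite directions, 17 genes were called. Across genes r was 0.56 and rho 0.68. Libraries of one site at the 2 ages share the fit but not mice. The type I interferon list was not called between the sites in young (adjusted p = 0.827) or aged mice (adjusted p = 0.792), and in both its median and mean were below 0 while camera gave the direction up. Median and mean also differed in sign for class II MHC (0.41 and -0.22), class I MHC (0.12 and -0.05) and plasma cell markers (0.47 and -0.48) between sites in young mice, for stem cell factors with age in bone-associated cells (0.28 and -0.37), and for senescence (-0.08 and 0.36) and heat shock genes (-0.04 and 0.02) with age in bone marrow, none of them called. In the interaction they differed for osteoclast markers (-0.55 and 0.08), NF-kB targets (0.02 and -0.20), type I interferon (0.10 and -0.01) and macrophage markers (-0.04 and 0.06), none called. For endothelial markers there, median and mean were -0.04 and -0.03 while camera gave the direction up.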

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

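The tests of patterns 1 and 3 and the splits were chosen only after the result was seen. For mature B cell and plasma cell genes the outcomes were written down before those genes were looked at.

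The age effect differed between the 2 sites, by the interaction test, for 45 genes. The named ones with a higher age effect in bone-associated cells were Jchain (7.04), Dtx1 (5.83), Igkc (5.67), Lax1 (4.24), Fgfr1 (4.18), Afap1l1 (3.72), Map7 (3.34), Flt3 (3.11), Ighm (3.02), Plac8 (1.64) and Cdkn1a (1.33). Those with a lower age effect there were Il10 (-3.20), Grap2 (-2.62), Acp5 (-2.29), Fnbp1l (-2.28), Fblim1 (-2.10) and Gzma, whose fitted value of -8.14 depends on the prior count because Gzma had no count in aged bone-associated libraries, so that its size is not a measurement. Few of these calls held without single libraries: Il10, Lax1, Acp5, Fnbp1l and Fblim1 each lost theirs in 10 of 12 such fits, Jchain in 9 and Igkc in 4. With DESeq2 673 genes were called, and with edgeR 7.07% of simulated 2-fold differences were recovered. The number of calls ran from 0 without young bone marrow replicate 3 to 170 without aged bone marrow replicate 2.

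Pattern 1 is the sex-linked genes. Loss of the Y chromosome from male cells would leave Xist near 0, but the lowest Xist count of an aged library was 1482. All 6 aged libraries held over 100 Xist counts and under 1% of the mean young Y-linked sum, as they would if the aged mice were female, so a wrong sex label is a candidate explanation. Whether the autosomal age differences stem from age or sex cannot be told apart, because no age group holds both sexes. Without X and Y genes 1171 genes were called in bone marrow, which bears on the linked genes only, and the difference in age stays open and untested.

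Pattern 2 is the immunoglobulin transcripts of aged libraries. More mature B cells would raise their other genes about as much as Igkc. In bone marrow the median of 6 such genes was -0.81 beside 2.52 for Igkc (2960 ± 1752 CPM with age). In bone-associated cells it was 1.00 (range -1.25 to 3.10) beside 8.20 (13064 ± 1290 CPM). Cd79a and Ms4a1 rose there, to 136 and 91.1 CPM. This argues against mature B cells with all 6 genes as the whole cause, not other B cells. Plasma cells, outside the gate, might account for it. Of 8 further plasma cell genes 2 were called higher in bone marrow (Txndc5 1.14, Ell2 0.65). In bone-associated cells 3 were (Eaf2 2.18, Pou2af1 2.11, Txndc5 1.06), too few to decide. Macrophages also express such secretory genes, and sex or age differences between the mice stay open.

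Pattern 3 is the activation genes in bone-associated libraries. A larger share of macrophages in that sort, as the whole cause, would raise activation genes no further than macrophage genes, which themselves ran from -0.23 to 2.28 for Csf1r in young and from -0.34 to 2.73 in aged mice. Of 73 activation genes 4 in young mice (Egr2, Il10, Fosb, Il1b) and 3 in aged mice (Nr4a2, Il1a, Nr4a3) exceeded the bound. As 5 were required, that cause stays open. After that result, the highest and lowest called lists of other cell types were compared. Their medians lay 6.49 apart in young mice (erythroid 3.04, basophil and mast cell -3.46, 6 of 12 lists called). In aged mice they lay 4.15 apart (osteoblast and stromal 2.71, T and NK cell -1.45, 4 of 12). As extremes were picked, only their opposite signs argue against macrophage share as the sites' only difference, not against it with other cells. A response to cell isolation that differed between the sites cannot be told apart from the site, since each fraction was prepared only in its own way, and in young bone-associated libraries 14 of 23 immediate early genes were higher and 4 lower.

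For each comparison 10 splits of the libraries were run, the real one included, too few for a share under 0.05. The real splits called 1209, 1581, 4523, 5419 and 45 genes in age in bone marrow, age in bone-associated cells, site in young mice, site in aged mice and the interaction. The highest of the other splits called 0, 1, 0, 0 and 0, so 1 split in each comparison, the real one, reached the real count. Among the site splits that part all 3 mice, the others called 0.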

How the results depend on the processing

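The fits without X and Y genes and without genes of other cell types were chosen only after the results were seen. Single genes were followed only where the fixed rule names them; genes named as examples of a list were not. In no alternative did a rule-named gene past the threshold turn its direction: of 179 such results, 137 stayed past it throughout, 30 lost it in another setting and 34 without 1 library. Without X and Y genes 1171, 1532 and 45 genes were called for age in bone marrow, age in bone-associated cells and the interaction. Without immunoglobulin genes and other markers the counts were 1198, 1513, 4428, 5353 and 31. The cause was not tested for the changes below, except where fewer libraries entered a fit. Depth was not varied. In simulations of this size, 22% to 37% of 2-fold and 62% to 76% of 4-fold changes were recovered in the age and site comparisons, and 7.07% and 51% in the interaction.

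Counts beyond 1.5 times the main ones were 2094, 2872 and 673 with the DESeq2 Wald test (age in bone marrow, age in bone-associated cells, interaction), 3252 and 7209 with limma-voom (age in bone marrow, site in young mice), 81 for the interaction with no filter and 960 for age in bone-associated cells with only the groups compared. With an estimated correlation 0, 0, 0, 2 and 0 lists passed, against 14, 23, 24, 23 and 13. With fry 4 passed in the interaction, and 29 (age in bone marrow) and 26 (interaction) changed in either direction. With the replicate block (the mouse for site and interaction, the shared number, which pairs no mice, for age), counts were 1122, 1422, 3984, 4708 and 57, and 13, 23, 26, 22 and 15 lists passed. Beyond the changes given in the report, the block lost endothelial markers with age in bone marrow (0.0633) and glycolysis in bone-associated cells (0.0510) and gained T and NK markers (0.0382) and Csf1r (0.0329) there.

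Results that reversed lay near 0 or were not past the threshold. For age in bone marrow, library size scaling gave Itgam -0.11, Ly6c1 -0.10, Ly6c2 -0.0522 and Csf1r -0.12, limma-voom gave Itgam -0.0210, Ly6c2 -0.0147 and Cd68 0.0517, and the fit of only the groups compared gave Csf1r -0.0040. For age in bone-associated cells, Itgam was 0.0147 with DESeq2 size factors, 0.0146 with the DESeq2 test and 0.0209 with the 5 CPM filter, and Il1a -0.0274 with library size scaling and -0.04625 with limma-voom. For site in young mice, library size scaling gave Mertk -0.33 and Siglec1 -0.10. In the interaction, limma-voom gave Il1rn 0.00096 and the replicate block Itgam 0.00033. Lists whose direction reversed, with adjusted p, were stem cell factors with age in bone-associated cells (0.376), type I interferon between sites in young (0.939) and aged mice (0.706) and NF-kB targets in the interaction (0.911), all with fry, and type I interferon in the interaction with the block (0.831).

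Leaving out 1 library gave 575 to 1414 calls for age in bone marrow, 739 to 1461 for age in bone-associated cells and 0 to 170 for the interaction. In age in bone marrow, values ran from -0.23 to 0.13 for Il1rn, -0.16 to 0.10 for Itgam, -0.47 to 0.39 for Ly6c1, -0.20 to 0.22 for Ly6c2, -0.11 to 0.22 for Csf1r and -0.20 to 0.14 for Cd68. In age in bone-associated cells they ran from -0.31 to 0.42 for Il1a, -0.23 to 0.14 for Il1rn, -0.16 to 0.17 for Itgam and -1.65 to 3.91 for Ly6c1. In site in young mice they ran from -0.28 to 0.0299 for Casp1, -0.99 to 2.92 for Ly6c1 and -0.12 to 0.18 for Mertk. In the interaction they ran from -0.22 to 0.15 for Il1rn, -0.21 to 1.47 for Il1r1, -0.45 to 0.0627 for Nlrp3, -0.45 to 0.12 for Tnf, -0.18 to 0.15 for Itgam, -1.71 to 3.85 for Ly6c1, -0.21 to 0.13 for Cd68, -0.26 to 0.0896 for Axl and -0.0260 to 0.51 for Siglec1.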

Other observations

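No test in this part was chosen after the result was seen, but the genes named here were.

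Cd14, the lipopolysaccharide co-receptor, was at 49.9 ± 9.21 CPM in young and 106 ± 26.4 in aged bone marrow and at 1360 ± 197 and 2416 ± 41.7 CPM in bone-associated cells (SD, n = 3). The Ly6C gene Ly6c2 was at 235 ± 28.5 CPM in young and 248 ± 76.5 CPM in aged bone marrow, although the gate excluded Ly6C.

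Counts of 6 eosinophil genes made up 0.464% ± 0.194 of young and 0.256% ± 0.0906 of aged bone marrow libraries, and 0.0701% ± 0.0168 and 0.0243% ± 0.00537 of bone-associated ones.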
